A study of Mus musculus with 28 samples.

How the data were processed

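RNA-seq was available for 7 libraries of V6.5 mouse ESCs: Tet2-WT (n = 3 independent ESC cultures), Tet2-Mut (n = 2 clones) and Tet2-KO (n = 2 clones), per the labels. The p-values rest on the spread between these, pooled over the Tet2-WT cultures and the clones. Replicate numbers only name the clones. The 3 bisulfite and 18 CUT&Tag samples of the series were not analysed here.

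The authors deposited a table of 17342 genes by 7 libraries in units of gene counts divided by DESeq2 size factors, a linear signal that is comparable between libraries. Per the submitters' processing notes, the tools included Trim Galore 0.6.5, STAR 2.7.3a, featureCounts and DESeq2 with the mm10 build; the annotation and the strand setting were not given in the sources used here. All values of the table were whole multiples of 1 step per library within a tolerance of 0.01 reads (100% of values in each library), so whole reads were recovered by dividing by that step. Size factors recomputed from the recovered reads equalled those of the deposited values. The recovered totals, 41.9 M to 58.5 M, count reads assigned to genes. Between 72.1% and 75.2% of the values from 1 to 20 reads were even, so the totals may count the mates of a read pair separately. Every gene in the table had at least 71 reads over the 7 libraries, so the table had been filtered before it was deposited. No pair of libraries agreed within sampling noise (chi-square per degree of freedom of at least 7.19). A count of 3 reads, a floor that was set and not measured, corresponds to normalized counts of 2.5 to 3.54.

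Gene symbols were matched to the RefSeq annotation of GRCm38.p6, the mm10 build, for chromosome and position; 16113 genes (92.9%) had a match. Differences between groups were tested with limma 3.58.1 in R 4.3.3 on log2(normalized count + 1), for 17338 genes with a value of at least 10 in at least 2 libraries. A single model of group means over all 7 libraries was used, with an empirical Bayes prior that follows the mean and Benjamini-Hochberg adjustment at 0.05. Fold changes are on this log2 scale and understate the change of low genes. With residual degrees of freedom of 4, the prior added 5.03. A group of 2 libraries shares the estimate of the spread with the other groups. The Tet2-WT cultures were closer to each other (chi-square per degree of freedom of 7.19, 7.71 and 13.4) than the Tet2-Mut clones (45.1) or the Tet2-KO clones (34.15). The shared estimate can therefore understate the spread between clones, and with it the p-values. Counts of overlap between comparisons that share libraries were set beside 50 simulated draws without differences and beside the overlap of independent lists. 

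A total of 24 gene lists was fixed before the data were examined and tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists and the 3 comparisons. With an estimated correlation 0 of the 33 list results past the threshold held. Fry, which asks whether a list's genes move on balance one way without comparing them with other genes, gave 17. Genes named in the text were chosen by a rule fixed before the data were examined. It took Tet2, then per comparison the 12 highest and 12 lowest log2 fold changes among genes past the test with a mean of at least 50 in the higher group, no overlap between the groups' libraries and no predicted-gene or clone name. It then took up to 4 members per list and comparison with the smallest p. Not every gene the rule takes is named. Members of a list beyond these, the genes named in the overlap counts, Ddx3y as the Y-linked example and genes given for the chromosome shifts were chosen after their values were seen.

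The steps were tested on simulated counts drawn from the real means and library sizes, with 50 genes at each of 4 fold sizes changed per comparison. The changed genes were taken from those with a mean normalized count above 50, so the recovery does not cover lower genes. For Tet2-KO against Tet2-WT (17306 genes), 98% of the genes changed 4-fold, 66% of those changed 2-fold and 44% of those changed 1.5-fold were recovered, with 5.33% false calls. For Tet2-Mut against Tet2-WT (17299 genes) these were 96%, 84%, 44% and 5.13%, and for Tet2-KO against Tet2-Mut (17301 genes) 98%, 76%, 30% and 9.46%. A simulated 2-fold rise of the fibroblast list was called in each comparison, with 0 of 23 other lists. Each gene was drawn independently, so this does not show how often lists of correlated genes would be called falsely. All libraries were drawn with the same spread per gene, although the Tet2-WT cultures lay closer together than the clones. The shares of false calls therefore need not hold for the real comparisons.

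Alternatives were other pseudocounts (0.5 and 10), other filters, upper quartile scaling, quantile normalization, only the 2 groups compared, a replicate block, no trend or a robust prior, minimum folds of 1.5 and 2, edgeR 4.0.16 (quasi-likelihood, TMM) and DESeq2 1.42.0 on the recovered reads, and each library left out in turn. Chosen after seeing the data were counting the called members of each list without each library in turn, leaving out the genes of chromosomes 8, 14 and Y and setting each chromosome's median equal across libraries.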

Results

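RNA-seq was analysed in 7 libraries of mouse embryonic stem cells (ESCs) of the V6.5 background, a male hybrid of the 129 and C57BL/6 strains, grown with serum and the self-renewal factor LIF. Tet2 encodes an enzyme that oxidizes 5-methylcytosine in DNA. The groups were Tet2-WT (n = 3), Tet2-Mut (n = 2 clones) and Tet2-KO (n = 2 clones). The series asks about functions of Tet2 that do not need its enzymatic activity, so Tet2-KO was compared with Tet2-Mut as well as each with Tet2-WT. The labels do not describe the mutation in Tet2-Mut. Cells had been kept on feeder fibroblasts, separated from them by pre-plating and held on gelatin overnight before RNA extraction. The recovered totals of reads assigned to genes were 58.5 M, 51.7 M and 41.9 M in Tet2-WT replicates 1, 2 and 3. They were 48.9 M and 52.9 M in Tet2-Mut replicates 1 and 2, and 48.3 M and 47.9 M in Tet2-KO replicates 1 and 2. The series also holds 3 whole-genome bisulfite and 18 CUT&Tag samples, which were not analysed here.

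Tet2 (chromosome 3, 133463677 to 133545136, mm10) was lower in both Tet2-KO libraries than in any other library. Its normalized count was 4915 ± 411 in Tet2-KO (SD, n = 2), 10890 ± 1029 in Tet2-WT (n = 3) and 11590 ± 2255 in Tet2-Mut (n = 2). The log2 fold change of Tet2-KO against Tet2-WT was -1.15 (SE 0.12, limma adjusted p = 0.00522), that against Tet2-Mut was -1.23 (adjusted p = 0.00382), and that of Tet2-Mut against Tet2-WT was 0.08 (adjusted p = 0.763). The counts cover the whole gene, so they do not show which exons the remaining Tet2-KO reads came from.

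**Figure D1:**
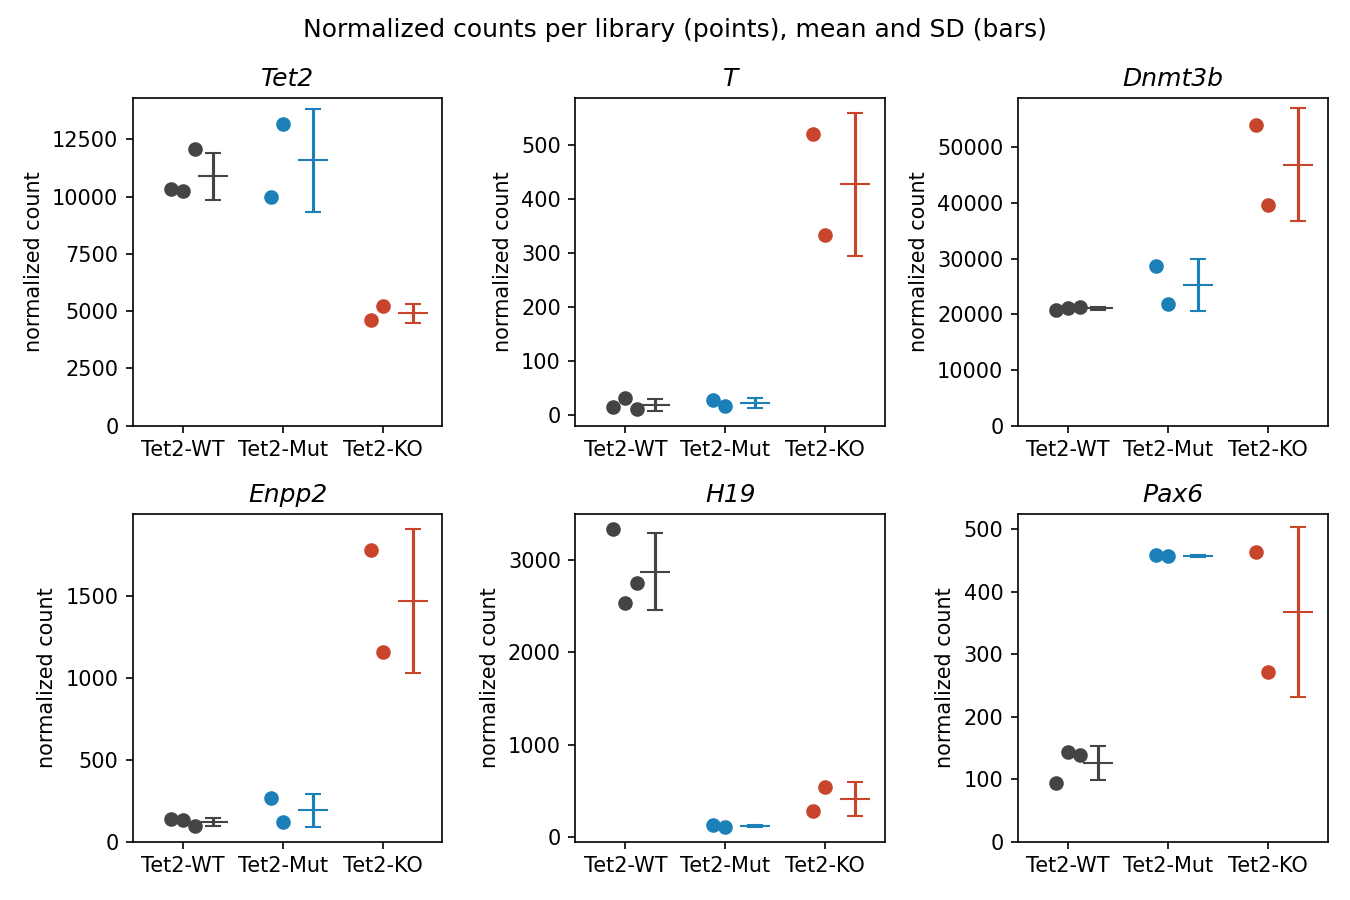
Normalized counts (vertical axes) of 6 genes in the 7 libraries, with each library as a point and the group mean with its SD as a bar beside it. Tet2 lies between 4624 and 5206 in the Tet2-KO libraries, T reaches 520 and 333 there, and H19 is lower in all Tet2-Mut and Tet2-KO libraries than in Tet2-WT.

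Against Tet2-WT, the Tet2-KO libraries had higher levels of 6 of 23 primitive streak and mesoderm genes, 12 of 20 formative and primed pluripotency genes and 12 of 27 fibroblast markers. These lists did not pass with an estimated correlation (camera adjusted p = 0.358, 0.365 and 0.365). The mesoderm factor T rose from 17.9 ± 10.8 normalized counts in Tet2-WT (SD, n = 3) to 427 ± 132 in Tet2-KO (n = 2), a log2 fold change of 4.62 (SE 0.51, adjusted p = 0.00522). Enpp2, the secreted enzyme that makes lysophosphatidic acid, rose from 122 ± 24.1 to 1466 ± 440 (log2 fold change 3.56, SE 0.34, adjusted p = 0.00522). The Wnt ligands Wnt8a and Wnt3 rose by log2 fold changes of 3.03 and 2.89, and Fgf8 and Lhx1, which act in gastrulation, by 2.88 each. The imprinted noncoding RNA H19 fell by 2.86 on the log2 scale (adjusted p = 0.00383), from 2872 ± 411 to 413 ± 182, and the meiotic genes Fkbp6 and Stra8 fell by 3.13 and 2.38. The other genes highest by fold were Sprr2a3, Actc1, Tmem200a, Gabra3, Gjb2 and Ms4a4d, with log2 fold changes between 2.91 and 4.57. Of these, all but Tmem200a lost their call without each Tet2-WT library and without Tet2-KO replicate 1, as did Fgf8 and Lhx1. At the lower end stood Muc2, Grin1, Slc4a9, Fhad1, Ceacam20, Ccdc113, Jsrp1, Slc6a14 and Pygl, between -3.41 and -2.19.

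Of 20 genes of formative and primed pluripotency, 12 were higher in Tet2-KO and 0 lower, or 15 and 2 adjusted over the list alone. Among them, the de novo methyltransferase Dnmt3b rose by 1.14 on the log2 scale (21050 ± 284 to 46860 ± 10150, adjusted p = 0.00564), Sox3 by 2.47, Sall2 by 1.92 and Pou3f1 by 1.43. The list's median log2 fold change was 0.91 (camera adjusted p = 1.28e-09, adjusted p = 0.365 with an estimated correlation). Of 23 primitive streak and mesoderm genes, 6 were higher and 0 lower (8 and 0 adjusted over the list alone, camera adjusted p = 0.000165, adjusted p = 0.358 with an estimated correlation). Of 15 Wnt targets, 5 were higher and 0 lower (6 and 0 adjusted over the list alone, camera adjusted p = 0.000345, adjusted p = 0.278 with an estimated correlation). Sp5 among them rose by 2.79 on the log2 scale, and T and Wnt3 stand in the streak list too. Of 28 naive and core pluripotency genes, Lin28a was higher and Tbx3 and Tdgf1 lower, with log2 fold changes of 0.73, -0.87 and -0.37. The list had 2 higher and 6 lower adjusted over the list alone (camera adjusted p = 0.0456, adjusted p = 0.62 with an estimated correlation). Beside these groups, the fibroblast markers of the feeder layer were also higher in Tet2-KO, where 12 of 27 rose and 0 fell (23 and 0 adjusted over the list alone). All 27 fold changes were positive (camera adjusted p = 2.08e-14, adjusted p = 0.365 with an estimated correlation). The collagen gene Col1a1 rose from 736 ± 44.8 to 1784 ± 480, Col5a1 from 1015 ± 180 to 3146 ± 840, and the smooth muscle gene Tagln from 270 ± 40.8 to 1402 ± 776. The median of these markers stood 1.53 above the Tet2-WT mean in Tet2-KO replicate 1 and 0.95 in Tet2-KO replicate 2. Without Tet2-KO replicate 1, the members past the test numbered 4 of the formative and primed genes, 1 of the streak genes, 1 of the Wnt targets and 2 of the fibroblast markers, all higher. Without Tet2-WT replicate 1, 2 or 3 they numbered 3 of the formative and primed genes each time, and 1, 2 and 0 of the fibroblast markers, the 0 by limma beside 21 with an unadjusted p under 0.05 and 0 by edgeR. Without Tet2-Mut replicate 1 they numbered 17 and 19. The streak genes past the test numbered 2 without each Tet2-WT library, and the Wnt targets 3, 2 and 3. Of the naive and core genes, limma called 0 without Tet2-WT replicate 1 or 3, where 10 and 9 had an unadjusted p under 0.05 and edgeR called 0, and 10 without Tet2-Mut replicate 1. T kept its call with each library left out in turn.

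Germline genes that DNA methylation silences in somatic cells were lower in Tet2-KO in 10 of 30 cases and higher in 1 (16 and 1 adjusted over the list alone). Their median log2 fold change was -0.61 (camera adjusted p = 3.94e-06, adjusted p = 0.358 with an estimated correlation). Stag3, a meiotic cohesin subunit, fell by 0.80, Tex14 by 0.83 and Tuba3a by 1.24 on the log2 scale. Without Tet2-KO replicate 1, 4 of these germline genes were lower and 0 higher, and the changed members ranged from 2 without Tet2-WT replicate 1 or 3 to 16 without Tet2-Mut replicate 1 or 2. The 8 two-cell-like genes measured all had negative fold changes, 2 of them past the test, Zscan4a and Tmem92 (4 adjusted over the list alone, camera adjusted p = 0.000166, adjusted p = 0.358 with an estimated correlation). Tmem92 was at 0 in both Tet2-KO libraries against 20.2 ± 3.33 in Tet2-WT. Without Tet2-WT replicate 1, 2 or 3, limma called 0 two-cell-like genes, where 4, 3 and 6 had an unadjusted p under 0.05 and edgeR called 0. It called 1 without Tet2-KO replicate 1 or 2. Of 39 imprinted genes, 8 were higher and 1, H19, lower (12 and 6 adjusted over the list alone, camera adjusted p = 0.0241, adjusted p = 0.566 with an estimated correlation). The higher ones held Meg3 and Rian, noncoding RNAs of one imprinted cluster, with log2 fold changes of 0.82 and 0.79, and Mest and Snrpn with 0.66 and 0.64. Neural and ectoderm genes were higher in 6 and lower in 1 of 21 cases, with Nes at a log2 fold change of 1.98 (8 and 3 adjusted over the list alone, camera adjusted p = 0.0145, adjusted p = 0.365 with an estimated correlation). Among 25 interferon-stimulated genes, 4 were higher, B2m, H2-K1 and H2-D1 among them (8 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.0166, adjusted p = 0.358 with an estimated correlation). Among 25 p53 targets, 5 were higher, with Plk2 at 0.76 and the apoptosis gene Bbc3 at 0.45 (8 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.00116, adjusted p = 0.365 with an estimated correlation). Without Tet2-KO replicate 1, limma called 0 interferon-stimulated genes and 0 p53 targets, where 9 and 10 had an unadjusted p under 0.05 and edgeR called 1 and 0. The p53 targets also fell to 0 by limma and edgeR without Tet2-WT replicate 1, 2 or 3, where 12, 10 and 8 had an unadjusted p under 0.05. The interferon-stimulated genes fell to 0 by limma and edgeR without Tet2-WT replicate 2, where 10 had an unadjusted p under 0.05, and to 1 without Tet2-WT replicate 1 or 3. Without Tet2-Mut replicate 1 or 2, the changed members numbered 9 of the interferon-stimulated, 17 of the imprinted and 9 of the neural genes, and without Tet2-WT replicate 1 or 2 they numbered 3 of the imprinted and 2 of the neural genes. They were 3 of each without Tet2-WT replicate 3, and 4 and 2 without Tet2-KO replicate 1.

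In the Sin3a complex, whose recruitment the series' title names, 1 of 24 genes passed, Ogt, which was lower by 0.36 on the log2 scale (0 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.786). Limma called 0 of them without Tet2-WT replicate 1, 2 or 3 or Tet2-KO replicate 1, where 4, 4, 5 and 3 had an unadjusted p under 0.05 and edgeR called 0. Among 9 Tet and Dnmt family genes, Dnmt3b and Tdg were higher and Tet2 lower (4 higher and 5 lower adjusted over the list alone, camera adjusted p = 0.786), and 7 changed without Tet2-Mut replicate 1 or 2. Trophectoderm genes were higher in 4 and lower in 3 of 19 cases (camera adjusted p = 0.825), with the keratins Krt8 and Krt18 at log2 fold changes of 1.60 and 1.36 and Rhox6 at -0.90. Limma called 0 trophectoderm genes without Tet2-WT replicate 1 or 3, where 8 and 9 had an unadjusted p under 0.05 and edgeR called 0. It called 1 without Tet2-WT replicate 2, 3 without Tet2-KO replicate 1 and 8 without Tet2-KO replicate 2. Extracellular matrix and adhesion genes were higher in 5 of 28 cases (9 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.00959, adjusted p = 0.62 with an estimated correlation). Their median was 0.38 in Tet2-KO replicate 1 and -0.02 in Tet2-KO replicate 2, where that of the fibroblast markers was 1.53 and 0.95, and the changed members ranged from 1 without Tet2-WT replicate 1 or 3 to 10 without Tet2-KO replicate 2. The integrated stress response list had 2 higher and 1 lower of 25 (camera adjusted p = 0.0361, adjusted p = 0.684 with an estimated correlation), and glycolysis 2 lower of 22 (camera adjusted p = 0.0247, adjusted p = 0.821 with an estimated correlation). Limma and edgeR called 0 of either list without Tet2-KO replicate 1, where 6 and 2 had an unadjusted p under 0.05. They also called 0 without Tet2-WT replicate 1, 2 or 3, where 8, 8 and 9 stress response and 5, 6 and 6 glycolysis genes had an unadjusted p under 0.05. Limma called 7 and 8 without Tet2-Mut replicate 1. Among 24 immediate early genes, 3 were higher and 2 lower, with 1 changed without Tet2-WT replicate 2 or 3 or Tet2-KO replicate 1. Of 22 endoderm genes, Fst and Lamb1 were higher, with 1 changed without Tet2-KO replicate 1 or any Tet2-WT library. Camera adjusted p was above 0.05 for Nodal and Lefty signalling (0.238), endoderm genes (0.463), Hox genes (0.315), cholesterol biosynthesis (0.463), immediate early genes (0.407), mitochondrially encoded genes (0.469) and Y-linked genes (0.403).

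In all, 1025 of 17338 genes differed between Tet2-KO and Tet2-WT by limma at an adjusted p under 0.05, 521 higher and 504 lower, and 375 of these differed by at least 2-fold (244 higher, 131 lower). Genes of chromosome 8 made up 14.7% of the changed genes against 4.97% of those tested, 140 of them lower and 11 higher in Tet2-KO. The count was 1992 with DESeq2 on the recovered reads, 19 without a mean trend in the prior variance and 2159 with only the 2 groups compared. It was 94, 99 and 85 without Tet2-WT replicate 1, 2 or 3, without Tet2-Mut replicate 1 or 2 it was 2160 and 2143, and without Tet2-KO replicate 1 it was 155.

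Against Tet2-WT, the Tet2-Mut cells had lower levels of 8 of 19 trophectoderm genes, and of single transcripts such as H19 and Nlrp4a. The list did not pass with an estimated correlation (camera adjusted p = 0.0836), and 2 of its genes passed without Tet2-WT replicate 1 or 2. H19 fell by 4.58 on the log2 scale (SE 0.24, adjusted p = 0.000254), from 2872 ± 411 normalized counts in Tet2-WT (SD, n = 3) to 119 ± 9.71 in Tet2-Mut (n = 2). The oocyte gene Nlrp4a fell by 4.58, from 95.7 ± 32.0 to 3.02 ± 1.55, and the X-linked homeobox gene Rhox6 fell by 2.74, from 1093 ± 180 to 163 ± 37.1. Pax6, a regulator of eye and neural development, rose from 126 ± 26.8 to 457 ± 1.37 (log2 fold change 1.88, adjusted p = 0.0168). Car2, a carbonic anhydrase, rose from 1564 ± 30.5 to 3952 ± 324 (1.33, adjusted p = 0.0141) and the neuroendocrine factor Insm1 by 1.49. Pax6, Car2, Insm1 and Nlrp4a lost their call without Tet2-WT replicate 1 or 2, and H19 kept it with each library left out. Other genes high by fold included Slitrk5, Plcb1, Smarca1, Hsd17b1, Dpp4, Fgf1 and Kcnj3, with log2 fold changes between 1.13 and 1.65. Those lowest were Xlr3a, Platr15, Fhad1, Fat2, Cdc42ep2, Usp26, Grin1, Aire and Aox3, between -3.61 and -2.95. Aire and Dnmt3l, which was also lower (log2 fold change -0.74, adjusted p = 0.0323), overlap on chromosome 10, and whether reads were counted by strand is not given in the sources used here.

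Of 19 trophectoderm genes, 8 were lower in Tet2-Mut and 0 higher (12 and 0 adjusted over the list alone), with a median log2 fold change of -0.81 (camera adjusted p = 4.1e-09, adjusted p = 0.0836 with an estimated correlation). Beside Rhox6 these included its neighbour Rhox9 (-2.39), the transcription factor Hand1 (-2.63) and the receptor Fgfr2 (-1.03). All 22 glycolysis genes had negative fold changes with a median of -0.45 (camera adjusted p = 3.56e-08, adjusted p = 0.551 with an estimated correlation), of which Hk1, a hexokinase, passed the test with -1.19 (9 lower adjusted over the list alone). The glycolysis median was -0.76 in Tet2-Mut replicate 2 and -0.13 in Tet2-Mut replicate 1. Cholesterol biosynthesis genes had a median of -0.20 with 1 of 25, Ebp, past the test (1 lower adjusted over the list alone, camera adjusted p = 7.48e-06, adjusted p = 0.384 with an estimated correlation). Genes of the integrated stress response were higher in 4 of 25 cases and lower in 0 (9 and 0 adjusted over the list alone, camera adjusted p = 0.000312, adjusted p = 0.551 with an estimated correlation). Among them were the one-carbon and serine enzymes Mthfd2 and Phgdh, with log2 fold changes of 0.58 and 0.31. The stress response median was 0.51 in Tet2-Mut replicate 2 and 0.06 in Tet2-Mut replicate 1. Limma called 0 of these genes without Tet2-Mut replicate 2, where 9 had an unadjusted p under 0.05, and 0 without Tet2-WT replicate 1, 2 or 3, where 9, 10 and 12 did, and edgeR called 0 each time. It called 15 without Tet2-Mut replicate 1. Imprinted genes were higher in 4 and lower in 3 of 39 cases (10 and 4 adjusted over the list alone, camera adjusted p = 0.0145, adjusted p = 0.551 with an estimated correlation). Meg3 was at 0.60, Phlda2 at 0.55, Igf2r at -0.43 and Peg3 at -0.69. The changed imprinted genes numbered 1 without Tet2-WT replicate 1 or 2, 2 without Tet2-WT replicate 3, and 10 higher and 5 lower without Tet2-Mut replicate 1. Among 25 p53 targets, Zmat3 and Sesn2 were higher (9 adjusted over the list alone, camera adjusted p = 0.000621, adjusted p = 0.365 with an estimated correlation). Among 21 neural genes Pax6 was higher (2 adjusted over the list alone, camera adjusted p = 0.0478, adjusted p = 0.384 with an estimated correlation). Fibroblast markers had a median of 0.46 with 0 of 27 past the limma test and 0 adjusted over the list alone (camera adjusted p = 0.00355, adjusted p = 0.633 with an estimated correlation). Of these, 6 had an unadjusted p under 0.05 and edgeR called 0. Their median was 0.67 in Tet2-Mut replicate 1 and 0.21 in Tet2-Mut replicate 2. The trophectoderm genes past the test numbered 2 without Tet2-WT replicate 1 or 2, 5 without Tet2-WT replicate 3 and 6 without Tet2-Mut replicate 2. With Tet2-WT replicate 1 left out, limma and edgeR called 0 glycolysis, cholesterol, p53 and neural genes, where 8, 7, 10 and 4 had an unadjusted p under 0.05. With Tet2-WT replicate 2 left out they also called 0, where 11, 3, 9 and 5 did. They called 0 cholesterol and p53 genes without Tet2-WT replicate 3, where 13 and 12 had an unadjusted p under 0.05, and without Tet2-Mut replicate 2, where 5 and 10 did. With Tet2-Mut replicate 1 left out, limma called 18 glycolysis, 7 cholesterol, 8 p53 and 6 neural genes and 2 fibroblast markers.

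Among the lists closest to the series' question, 2 of 24 Sin3a complex genes were higher in Tet2-Mut, Ing1 and Sap30, with log2 fold changes of 0.40 and 0.30 (3 higher adjusted over the list alone, camera adjusted p = 0.0926). Both lie on chromosome 8, whose genes were shifted as a whole in these libraries. Dnmt3a was higher by 0.60 and Uhrf1, which keeps DNA methylation through replication, lower (log2 fold change -0.30), as 1 higher and 2 lower of 9 Tet and Dnmt family genes (2 and 3 adjusted over the list alone, camera adjusted p = 0.606). Tbx3 and Nanog were lower by log2 fold changes of -1.17 and -0.37 and Fbxo15 higher by 0.37 among 28 naive and core pluripotency genes (camera adjusted p = 0.879). Of 30 germline genes 4 were lower and 0 higher, Tuba3a, Smc1b, Fkbp6 and Xlr3a (camera adjusted p = 0.383), and of 25 interferon-stimulated genes Trim25 and Xaf1 were lower (camera adjusted p = 0.315). Sox4 was higher among the formative and primed genes (camera adjusted p = 0.105), Notum among the Wnt targets (0.887), and Eomes was lower among the streak genes (0.558) and Id2 among Nodal and Lefty genes (0.369). With Tet2-WT replicate 1 left out, limma and edgeR called 0 genes of these 9 lists, where 3, 4, 7, 9, 6, 3, 4, 5 and 4 had an unadjusted p under 0.05, in the order given. With Tet2-WT replicate 2 left out they called 0 as well, where 3, 5, 7, 8, 5, 3, 4, 4 and 4 did. With Tet2-WT replicate 3 left out, limma called 1 naive and 1 Wnt gene, and 0 of the other 7 lists by either tool, where 5, 5, 10, 8, 5, 6 and 4 did. With Tet2-Mut replicate 2 left out, both tools called 0 Sin3a, Tet and Dnmt, interferon and streak genes, where 6, 6, 4 and 4 did, and limma called 2 germline genes. With Tet2-Mut replicate 1 left out, limma called 5, 5, 10, 9, 6, 5, 4, 4 and 6 genes of the 9 lists. Camera adjusted p was also above 0.05 for two-cell-like genes (0.667), endoderm genes (0.786), Hox genes (0.267), immediate early genes (0.051), extracellular matrix and adhesion genes (0.751), mitochondrially encoded genes (0.254) and Y-linked genes (0.181).

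In all, 594 genes differed between Tet2-Mut and Tet2-WT by limma, 250 higher and 344 lower, and 168 of these by at least 2-fold (21 higher, 147 lower). Chromosome 8 held 23.9% of the changed genes, 136 higher and 6 lower, and with the chromosome medians equalized across libraries, a step chosen after seeing the data, 421 genes differed, 23.5% of them higher against 42.1% before. The count was 1555 with DESeq2 on the recovered reads, 900 with only the 2 groups compared and 0 by limma without a mean trend in the prior variance, where 3018 genes had an unadjusted p under 0.05, against 582 with edgeR. Without Tet2-WT replicate 1, 2 or 3 it was 7, 6 and 123, and without Tet2-Mut replicate 1 or 2 it was 2198 and 219.

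**Figure D2:**
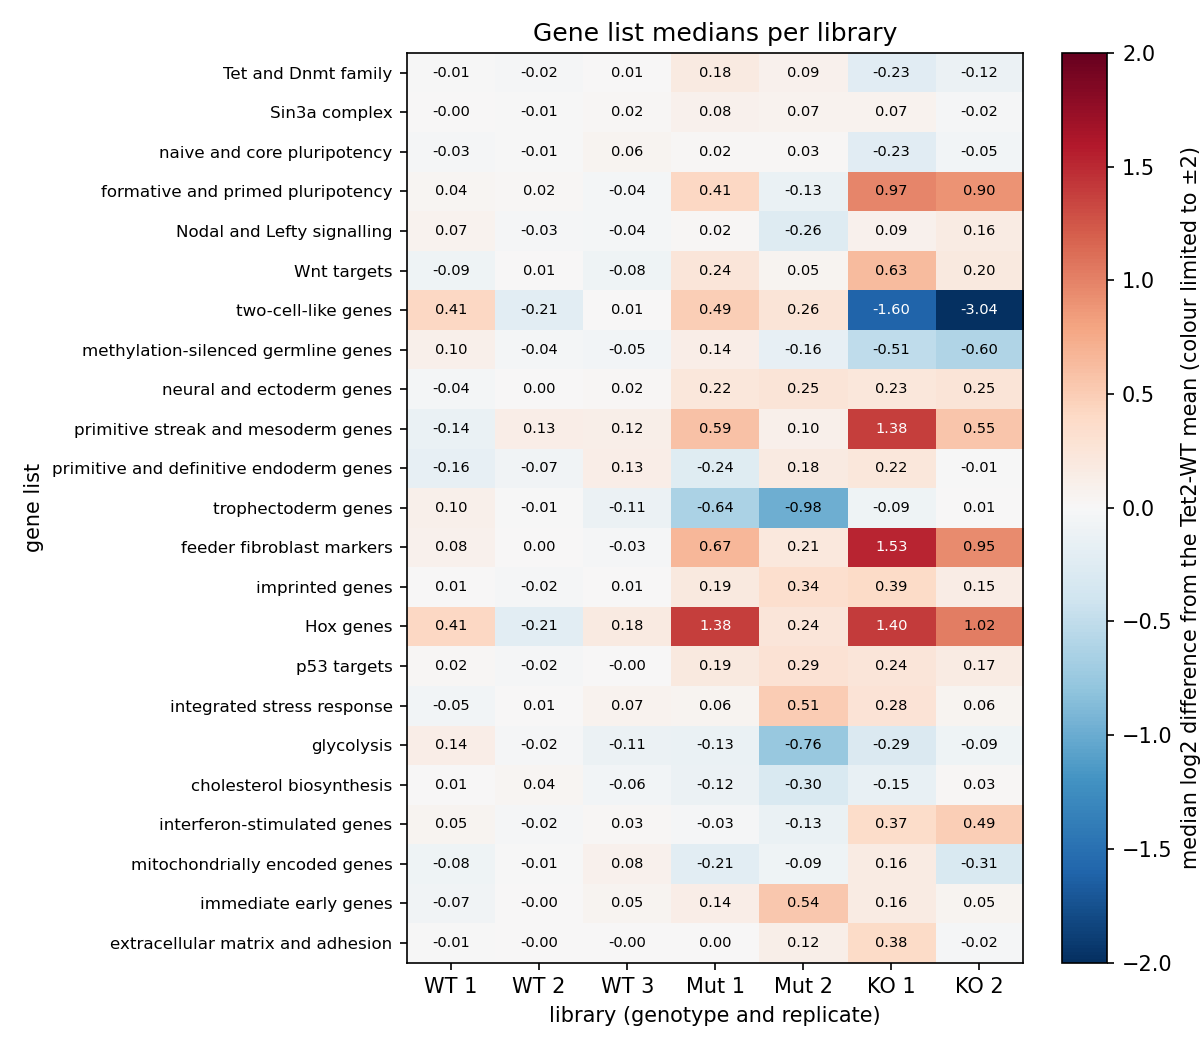
Median log2 difference from the Tet2-WT mean (colour and number) of 23 gene lists (vertical axis) in each of the 7 libraries (horizontal axis, genotype and replicate). Fibroblast markers stand at 1.53 and 0.95 in the Tet2-KO libraries, trophectoderm genes at -0.64 and -0.98 in the Tet2-Mut libraries, and formative and primed genes at 0.97 and 0.90 in Tet2-KO.

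Compared directly, Tet2-KO libraries had higher levels than Tet2-Mut libraries of 6 of 23 streak genes, 8 of 19 trophectoderm genes and 7 of 25 interferon-stimulated genes. These lists did not pass with an estimated correlation (camera adjusted p = 0.384, 0.0836 and 0.278). Without Tet2-WT replicate 2, limma and edgeR called 0 interferon-stimulated genes, where 11 had an unadjusted p under 0.05. T was 427 ± 132 normalized counts in Tet2-KO (SD, n = 2) and 21.6 ± 8.75 in Tet2-Mut (n = 2), a log2 fold change of 4.26 (SE 0.55, adjusted p = 0.00457). Lhx1 was 78.5 ± 7.40 against 3.99 ± 0.184 (3.99, adjusted p = 0.00473). The interferon-inducible GTPase genes Gbp2b and Gbp2, neighbouring paralogs whose reads can be shared, were higher by log2 fold changes of 4.46 and 3.53. Fgf5, a marker of primed cells, was higher by 3.85 (adjusted p = 0.0384), with a wide spread between the Tet2-Mut replicates (122 ± 148). It lost its call in 13 alternatives, among them edgeR and DESeq2, with an adjusted p of up to 0.186. The other genes highest by fold were Sprr2a3, Piezo2, Actc1, Chst1, Usp26, Wnt8a and Enpp2, between 2.99 and 4.37. Of these Chst1, Sprr2a3 and Actc1 lost their calls in 14, 13 and 8 alternatives. The amino acid transporter Slc6a14 had a log2 fold change of -3.25, the meiotic gene Stra8 had a log2 fold change of -2.18 and the neural factor Sox1, on chromosome 8, -2.40. Others at the lower end included Pou4f2, also on chromosome 8, Rgs20, Dync1i1, Insc, Halr1, Robo4, Fitm1 and Pdyn, between -2.83 and -1.98. Fitm1 lies on chromosome 14, whose genes had a higher median in Tet2-Mut replicate 2.

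Of 19 trophectoderm genes, 8 were higher in Tet2-KO than in Tet2-Mut and 0 lower (10 and 0 adjusted over the list alone), with a median log2 fold change of 1.02 (camera adjusted p = 3.94e-10, adjusted p = 0.0836 with an estimated correlation). They were Rhox6, Rhox9, Hand1 and Fgfr2, which were lower in Tet2-Mut than in Tet2-WT, Krt8, Krt18 and Cdx2, which were higher in Tet2-KO than in Tet2-WT, and Krt19. Formative and primed genes were higher in 7 and lower in 1 of 20 cases (9 and 1 adjusted over the list alone, camera adjusted p = 3.45e-07, adjusted p = 0.388 with an estimated correlation), with Dnmt3b at a log2 fold change of 0.89. Of 23 streak and mesoderm genes 6 were higher (7 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.00381, adjusted p = 0.384 with an estimated correlation). Of 15 Wnt targets 5 were higher (7 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.00115, adjusted p = 0.278 with an estimated correlation). Fibroblast markers were again higher, in 4 of 27 cases with a median of 0.75 (10 adjusted over the list alone, camera adjusted p = 2.75e-07, adjusted p = 0.461 with an estimated correlation). Interferon-stimulated genes were higher in 7 of 25 cases and lower in 0 (8 and 0 adjusted over the list alone, camera adjusted p = 8e-04, adjusted p = 0.278 with an estimated correlation). They included the chemokine Cxcl10 (log2 fold change 2.45), the immunoproteasome subunit Psmb8 (2.65) and the antigen presentation genes B2m (0.85) and H2-K1 (0.70). Without Tet2-KO replicate 1 the members past the test numbered 2 interferon-stimulated, 2 formative and primed, 2 fibroblast, 2 Wnt target and 7 trophectoderm genes, all higher, and without Tet2-Mut replicate 2 they numbered 1, 4, 2, 3 and 9 higher. The streak genes numbered 4 without Tet2-KO replicate 1. Leaving out Tet2-WT replicate 1, 2 or 3, limma called 1, 0 and 3 interferon-stimulated genes, the 0 beside 11 with an unadjusted p under 0.05 and 0 by edgeR, 4 formative and primed genes each time, and 3, 2 and 4 Wnt targets. Without Tet2-KO replicate 2 it called 3 interferon-stimulated genes, 2 Wnt targets and 8 fibroblast markers, and without Tet2-Mut replicate 1 it called 15 formative and primed genes and 10 fibroblast markers.

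Germline genes were lower in Tet2-KO than in Tet2-Mut in 7 of 30 cases and higher in 0, and Piwil2, a piRNA pathway gene, had a log2 fold change of -1.35. Piwil2 lies on chromosome 14, whose genes had a higher median in Tet2-Mut replicate 2. Its normalized counts were 1518 and 2496 in Tet2-Mut replicates 1 and 2. The list had 2 higher and 12 lower adjusted over the list alone (camera adjusted p = 0.000312, adjusted p = 0.365 with an estimated correlation). The changed germline genes ranged from 3 without Tet2-WT replicate 1 or 2 or Tet2-KO replicate 1 to 11 without Tet2-Mut replicate 1, 4 higher and 7 lower. All 8 two-cell-like genes had negative fold changes, 3 of them past the test (6 adjusted over the list alone, camera adjusted p = 5.17e-05, adjusted p = 0.358 with an estimated correlation). Limma called 0 of them with genes on chromosomes 8, 14 and Y left out, and also without Tet2-WT replicate 1, 2 or 3, where 6 had an unadjusted p under 0.05 each time and edgeR called 0. The same held without Tet2-KO replicate 2, where limma and edgeR called 0 and 5 had an unadjusted p under 0.05, and limma called 1 without Tet2-Mut replicate 1 or 2. Extracellular matrix and adhesion genes were higher in 4 and lower in 1 of 28 cases (8 and 2 adjusted over the list alone, camera adjusted p = 0.0204, adjusted p = 0.638 with an estimated correlation), with 2 changed without Tet2-WT replicate 1 or 2, 1 without Tet2-WT replicate 3 and 12 without Tet2-Mut replicate 1. The balance turned to 2 higher and 3 lower without Tet2-KO replicate 1. Glycolysis and cholesterol biosynthesis genes had positive medians of 0.30 and 0.24 with 0 members of either past the limma or edgeR test (camera adjusted p = 0.00536 and 0.0033, adjusted p = 0.781 and 0.566 with an estimated correlation). Of their members 6 and 9 had an unadjusted p under 0.05. The glycolysis list turned direction without Tet2-Mut replicate 2 (camera adjusted p = 0.693) and was not past the threshold without Tet2-KO replicate 2 (0.305), while 12 glycolysis and 9 cholesterol genes were higher without Tet2-Mut replicate 1. Tet1 was lower in Tet2-KO than in Tet2-Mut (log2 fold change -0.57, adjusted p = 0.00787) and Dnmt3b higher among 9 Tet and Dnmt family genes (camera adjusted p = 0.893). Of 24 Sin3a complex genes, Sap30 and Ing1 of chromosome 8 were lower, with -0.55 and -0.48 (camera adjusted p = 0.326). Both values lay near the chromosome 8 median of -0.54 in this comparison, and the fold change of Ing1 became 0.07 with the chromosome medians equalized. In this complex 4 genes changed without Tet2-Mut replicate 1. Camera adjusted p was above 0.05 for naive and core pluripotency (0.057), Nodal and Lefty signalling (0.0645), neural (0.355), endoderm (0.309), imprinted (0.469), Hox (0.891), p53 target (0.908), integrated stress response (0.259), immediate early (0.558), mitochondrially encoded (0.786) and Y-linked (0.786) genes.

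In all, 1074 genes differed between Tet2-KO and Tet2-Mut by limma, 458 higher and 616 lower in Tet2-KO, and 364 of these by at least 2-fold (248 higher, 116 lower). Chromosome 8 held 37.2% of them, 396 lower and 3 higher, and with the chromosome medians equalized across libraries, chosen after seeing the data, 483 genes differed, 65.4% of them higher against 42.6% before. The count was 1808 with DESeq2, 10 without a mean trend in the prior variance and, with only the 2 groups compared, 0 by limma, where 2357 genes had an unadjusted p under 0.05, against 1054 with edgeR on all libraries. Without Tet2-WT replicate 1, 2 or 3 it was 605, 530 and 661, without Tet2-Mut replicate 1 it was 2679, and without Tet2-KO replicate 1 it was 552.

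Genes changed the same way in Tet2-KO and Tet2-Mut against Tet2-WT numbered 118, 32 higher and 86 lower. They held H19, Tbx3, the trophectoderm genes Rhox6, Rhox9 and Lgals3, the germline genes Fkbp6 and Tuba3a and the glycolytic enzyme Hk1 on the lower side, and Pax6, Car2, Sox4, Meg3, Rian, Sesn2, Zmat3 and Slitrk5 on the higher side. Among them, 5 also differed between Tet2-KO and Tet2-Mut, namely H19, Rhox6, Rhox9, Zc3hav1 and Mapt, with H19 at a log2 fold change of 1.72 (adjusted p = 0.00788). Independent lists of these sizes would share 17.5 genes, but both comparisons use the same Tet2-WT libraries, so their lists are not independent. The 50 simulated draws without differences gave 0 such genes each, which sets no expected overlap for lists of these sizes either. Across genes, which are not independent replicates, the covariance of the fold changes was 0.126 against 0.0542 in simulated groups without differences. Their correlation of 0.415 lay within the simulated range of 0.366 to 0.435. All 7 libraries were drawn anew with a pooled spread per gene, although the Tet2-WT cultures lay closer together than either pair of clones. The simulated covariance and correlation can therefore be too high for the shared Tet2-WT libraries. The 3 Tet2-WT libraries shared by both comparisons are too few to be split into separate control groups of 2. Without Tet2-WT replicate 1, 2 or 3 the count of 118 became 1, 1 and 7, without Tet2-Mut replicate 1 it was 367, and without Tet2-KO replicate 1 or 2 it was 44 and 275. The balance moved too, to 22 higher and 22 lower without Tet2-KO replicate 1 and 5 higher and 2 lower without Tet2-WT replicate 3.

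**Figure D3:**
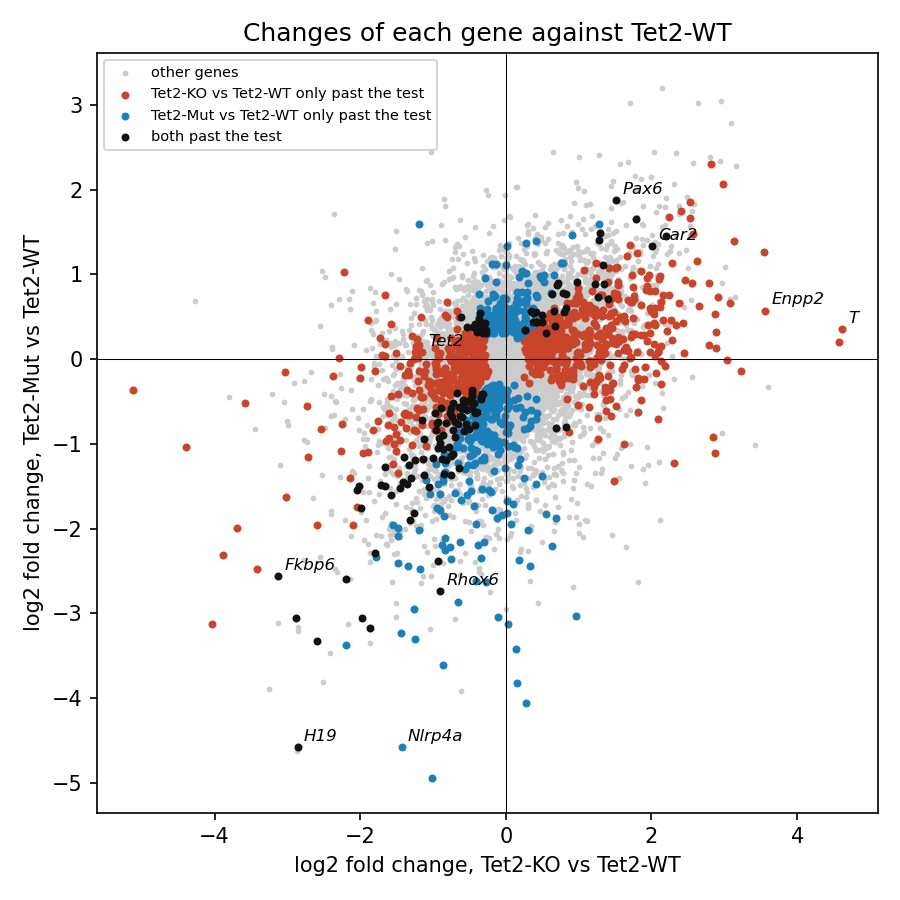
Log2 fold change of each of the 17338 genes tested in Tet2-KO (horizontal axis) and in Tet2-Mut (vertical axis), both against Tet2-WT, with genes past the limma test in one or both comparisons coloured. T lies far to the right (4.62) near 0 on the vertical axis (0.36), and H19 lies low in both (-2.86 and -4.58).

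Genes that separated Tet2-KO from both other genotypes in the same direction numbered 406, 194 higher and 212 lower, and 384 of them were not past the test between Tet2-Mut and Tet2-WT. The higher ones included T, Wnt3, Wnt8a, Sp5, Fgf8, Lhx1, Enpp2, Gbp2, Dnmt3b, Pou3f1, Sox3, Sall2, Krt8, Krt18, Cdx2, Col1a1 and Tagln. The lower ones included Tet2 itself, Stra8, Slc6a14, Zscan4a and the germline genes Piwil2, Tex14, Dpep3, Syce1, Stag3 and Hsf2bp, while 116 of the 212 lay on chromosome 8. Independent lists would share 31.7 genes, but both comparisons use the same Tet2-KO libraries, so their lists are not independent. The 50 simulated draws gave 0 such genes each, which sets no expected overlap for lists of these sizes either. The correlation of the 2 sets of fold changes was 0.599 against 0.515 to 0.575 in simulated unchanged groups, and their covariance 0.206 against 0.0803. The pooled spread of these draws can be too small for the shared Tet2-KO libraries, so the simulated values can be too low. With the chromosome medians equalized the count was 233, with 63.5% higher against 47.8% before, and with genes on chromosomes 8, 14 and Y left out it was 229. It was 58, 56 and 51 without Tet2-WT replicate 1, 2 or 3, without Tet2-Mut replicate 1 it was 936, and without Tet2-KO replicate 1 it was 93.

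Whole chromosomes differed between the genotypes in the median level of their genes. The median over 741 expressed chromosome 8 genes stood 0.29 and 0.28 above the Tet2-WT mean on the log2 scale in Tet2-Mut replicates 1 and 2, and at -0.28 and -0.24 in Tet2-KO replicates 1 and 2. The Tet2-WT libraries lay at -0.04, -0.02 and 0.06. Between Tet2-KO and Tet2-Mut the chromosome 8 median was -0.54. The median over 468 chromosome 14 genes was 0.51 in Tet2-Mut replicate 2 and -0.06 in Tet2-Mut replicate 1. The Y-linked gene Ddx3y was at 623, 595 and 661 normalized counts in Tet2-WT. It was at 1655 and 5.79 in Tet2-Mut replicates 1 and 2, and at 43.4 and 2143 in Tet2-KO replicates 1 and 2. Over the 5 expressed Y-linked genes the median was 2.01 and -6.53 in Tet2-Mut replicates 1 and 2. In Tet2-KO replicates 1 and 2 this median was -2.98 and 1.34. The level of these genes thus followed the single library and not the genotype.

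**Figure D4:**
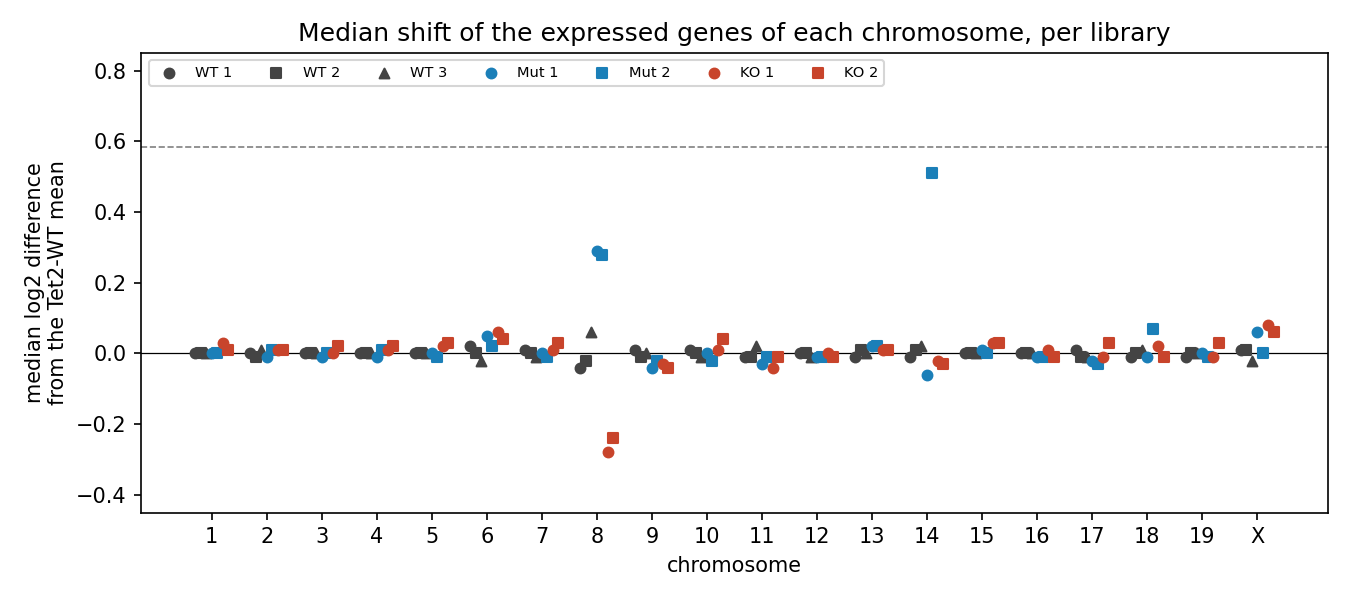
Median log2 difference from the Tet2-WT mean (vertical axis) over the expressed genes of each chromosome except Y (horizontal axis), 1 point per library, coloured by genotype with a marker per replicate. Chromosome 8 is at 0.29 and 0.28 in Tet2-Mut and -0.28 and -0.24 in Tet2-KO, chromosome 14 is at 0.51 in Tet2-Mut replicate 2, and the dashed line marks 0.585, the log2 of 3 over 2.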

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

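The windows along chromosomes 8 and 14 were fixed before their values were seen; all other tests in this part were chosen after the results were seen.

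Chromosome 8 was singled out because its genes moved one way in every Tet2-Mut library (0.29 and 0.28 on the log2 scale) and the opposite way in every Tet2-KO library (-0.28 and -0.24); the difference itself was not tested. Of the 13 windows of 10 Mb with at least 10 expressed genes, 13 (100%) had a median below -0.2 for Tet2-KO against Tet2-Mut. They ranged from -0.63 to -0.49. Of the 11 chromosome 14 windows of Tet2-Mut replicate 2, 90.9% lay above 0.2. The window from 0 to 10 Mb, with 17 genes, lay the other way at -0.27. A different number of copies of chromosome 8, and of part of chromosome 14, is a candidate explanation (3 copies over 2 give 0.585). Scaling of the libraries is argued against by the other autosomes apart from chromosome 14, whose largest median for Tet2-KO against Tet2-Mut was 0.042 in size and whose medians in single libraries lay within 0.07 of 0, and regulation of single genes by the 91.4% of expressed chromosome 8 genes that were lower in Tet2-KO. The Tet2-KO to Tet2-Mut median was -0.54, while each genotype lay by less than that from Tet2-WT, and DNA copy number was not measured here. Both Tet2-Mut clones and both Tet2-KO clones share their chromosome 8 shift, so a karyotype difference and the genotype go together for these genes. Any effect of it on genes of other chromosomes would go together with the genotype too. Leaving out or centring the chromosome 8 genes cannot separate them.

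Another 22 genes were singled out because they changed in opposite directions in Tet2-KO and Tet2-Mut against Tet2-WT. Chromosome 8 held 19 of them, all lower in Tet2-KO, and the other 3 were Krt19 (log2 fold changes 0.69 in Tet2-KO and -0.81 in Tet2-Mut), Gprc5c (0.82 and -0.81) and Spry4 (-0.62 and 0.50).

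The rise of fibroblast markers in Tet2-KO was weighed because the cells had grown on feeders before pre-plating. If feeder cells were the only source, the called markers would rise in 1 ratio between the 2 Tet2-KO libraries. The heterogeneity of that ratio was 0.671 per degree of freedom against a 95% point of chance of 1.79. The noise of each ratio came from the model's spread, which includes the difference between these same 2 libraries and so favours a low value. The test therefore does not decide whether there was a single source. The ratios ran from 0.943 for Thbs2 to 4.38 for Cnn1, and Col1a1 was at 1784 in Tet2-KO against 736 in Tet2-WT. Of the 27 markers, 20 had a Tet2-WT mean of at least 50 and 0 are in another list, and carry-over was not weighed for the matrix and adhesion genes. Carry-over and expression of these genes by the Tet2-KO cells cannot be told apart, because no library of feeder cells was analysed here.

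The rise of the 18 formative, primed and streak genes called higher in Tet2-KO than in Tet2-WT was weighed for the same reason, with 3 of the 18 on chromosomes 8, 14 or Y. They were picked by that call from these same libraries, which favours a larger rise in Tet2-KO than elsewhere. Per unit rise of the fibroblast markers, these genes rose in Tet2-Mut replicate 1 by 75.3% of their rise in Tet2-KO. They moved the other way in Tet2-Mut replicate 2 (-53.1%). Both values are ratios of median log2 differences, whereas carried-over reads would add to the counts themselves, so they cannot measure carry-over. Carry-over of feeder cells, or any state that raises both groups of genes, may contribute and is not decided by these libraries. An uneven state of 1 Tet2-KO clone stays open for the streak genes. Over all of them measured, the median of Tet2-KO replicate 2 (0.55) lay above the Tet2-WT libraries (-0.14 to 0.13) but below Tet2-Mut replicate 1 (0.59), a gap of -0.04. Over all formative and primed genes both Tet2-KO libraries (0.97 and 0.90) lay above every other library, the highest being Tet2-Mut replicate 1 at 0.41. With the Tet2-WT libraries at -0.04 to 0.04, this argues against a rise in only 1 Tet2-KO clone for that list. A difference between clones unrelated to Tet2 cannot be told apart from the genotype with 2 clones of it.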

How the results depend on the processing

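Leaving out genes of chromosomes 8, 14 and Y, equalizing chromosome medians and leaving out a library for the gene lists were chosen after seeing the data. The other alternatives were planned. The 5 counts of changed genes are given in the order Tet2-KO against Tet2-WT, Tet2-Mut against Tet2-WT, Tet2-KO against Tet2-Mut, the same way in both, and Tet2-KO against both; they were 1025, 594, 1074, 118 and 406. They stayed within 1.5 times of these with other pseudocounts, filters, upper quartile or quantile scaling, a robust prior and edgeR. With DESeq2 they were 1992, 1555, 1808, 423 and 848, and with only the 2 groups compared 2159, 900, 0, 319 and 0; the cause was not tested. Without the trend they were 19, 0, 10, 0 and 7, where the prior degrees of freedom fell from 5.03 to 1.45. At least 2-fold left 375, 168, 364, 35 and 139, and at least 1.5-fold 680, 322, 77 and 246 for all but Tet2-KO against Tet2-Mut. Leaving out chromosomes 8, 14 and Y gave 384 for Tet2-Mut against Tet2-WT, 480 for Tet2-KO against Tet2-Mut and 229 for Tet2-KO against both. Equalizing chromosome medians gave 483 and 233 for the latter pair. On chromosome 8, 396 of the 1074 calls were lower and 3 higher, and on chromosome 14, 11 were higher and 13 lower. Chromosome Y held 0. The drop to 480 exceeds these, so calls on other chromosomes were lost as well. The prior and the adjustment both depend on the genes tested together, and which of them acted was not tested. With 1 library left out, the counts ranged from 85 to 2160, 6 to 2198, 530 to 2679, 1 to 367 and 51 to 936; a lone remaining library was then assumed to vary like the others. The covariance of fold changes of 0.126 was 0.13 after quantile normalization and 0.0828 with a minimum of 50; the cause was not tested.

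The replicate numbers do not pair the clones: correlations of deviations between same-numbered libraries lay between -0.073 and 0.087. With the replicate block the 5 counts were 15, 7, 467, 1 and 12, and 55 of 222 named gene results kept their call, where the block takes up degrees of freedom and Tet2-WT replicate 3 has no partner.

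Of 33 list results past the threshold among 72, 0 kept their call with an estimated correlation and 15 with fry, which called 17 in all. Some also lost their call with any single library left out, the largest number of them without Tet2-KO replicate 1. Under one alternative each, 3 results reversed: Cdh1 and Ing1 between Tet2-KO and Tet2-Mut became 0.21 and 0.0694 on the log2 scale with chromosome medians equalized, both being chromosome 8 genes. The glycolysis list in the same comparison turned direction without Tet2-Mut replicate 2 (adjusted p = 0.693, against 3.7e-09 without Tet2-Mut replicate 1 and 0.305 without Tet2-KO replicate 2); the cause was not tested. Of 222 named gene results, 215 kept their call with edgeR and 219 with DESeq2, but 5 without the trend, 141 with only the 2 groups compared and 185 with chromosome medians equalized. Without Tet2-WT replicate 1, 2 or 3, 83, 79 and 96 kept it, without Tet2-Mut replicate 1 or 2, 214 and 159, and without Tet2-KO replicate 1 or 2, 136 and 179. Tet2, Enpp2, Dnmt3b and H19 in Tet2-KO against Tet2-WT kept theirs in all alternatives but the one without the trend. Depth limits genes with a few reads, such as two-cell-like genes.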

Other observations

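Several genes stood out beyond the lists of the report, as values without an explanation. Among those lower in both Tet2-Mut and Tet2-KO were Gpat2, an acyltransferase of the germline, at 341 normalized counts in Tet2-WT, 74.7 in Tet2-Mut and 103 in Tet2-KO, and the ciliary gene Hydin, on chromosome 8, at 204, 73.9 and 50.6. The T cell kinase gene Zap70 was at 326, 116 and 101, and the acinar transcription factor gene Bhlha15 at 282, 101 and 93.0. Among genes that separated Tet2-KO from both other genotypes, the receptor gene Ror1 was at 98.8 in Tet2-WT, 107 in Tet2-Mut and 435 in Tet2-KO, and the lymphotoxin gene Ltb was at 86.5, 74.4 and 353. These genes were chosen after their values were seen.

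On the first principal component of the log2 values, which holds 31.3% of the variance, Tet2-KO replicate 1 lay at 64.7 and Tet2-KO replicate 2 at 30.7, and the other libraries between -28.1 and 0.63. On the second, with 28.9%, Tet2-Mut replicate 2 lay at -68.5 and the other libraries between -11.6 and 29.9.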
